A study of Mus musculus with 8 samples.

How the data were processed

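The data are messenger RNA profiles of serotonin (5-HT) neurons of the mouse dorsal raphe, from adult C57BL/6 mice of 2 to 3 months. Per the labels' protocols, YFP-positive neurons were sought in acute coronal slices, the whole soma was drawn into a patch pipette, and the cDNA was made with a SMARTer Ultra Low RNA kit, which amplifies the RNA of very small samples, before Illumina libraries were prepared. The labels give 4 libraries as wildtype and 4 as Pten-deficient. Each library is titled as 1 neuron and no animal is named.

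The authors deposited 1 table of 5814 genes by 8 libraries. TopHat2 and Cufflinks and the mm9 mouse genome build are named in the submitters' processing notes; their versions, the gene annotation and the settings are not given in the sources used here. The deposited table is named for FPKM, fragments scaled to transcript length and to the total of mapped fragments, but its values are on a log2 scale. They run from 0 to 13.47, and raising 2 to each value and subtracting 1 gives sums of 230626 to 478181 FPKM per library, while a natural log would give sums of 3.25e+06 to 7.8e+06. The deposited values are therefore read here as log2(FPKM + 1). The lowest mean over the 8 libraries is 1.00 on that scale, so the table holds only genes with a mean of at least 1; genes below that mean were not analysed here. All 8 columns were matched to samples by the labels. No pair of libraries held identical values. The table lists 3 symbols on 2 rows each, which were kept as separate rows, and 13 names that had been turned into dates, which were not named here. It holds no mitochondrially encoded gene.

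No read counts were used, and the depth of each library is unknown. Values reach as low as 2.56e-15 above 0, so they are not whole multiples of the value of 1 read, and no counting interval could be made. A listed 0 can be a failed estimate: of 23 widely expressed genes checked, 0 to 6 per library were listed at 0. For genes with any listed 0, the value of each library, the range or the difference is given, with no mean and SD.

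Because each library is 1 neuron and the animals are not named, each genotype counts as 1 sample. No test between genotypes was made, and no p-value, standard error or number of changed genes was computed from the cells. The SDs describe the spread between 4 neurons of a genotype. A difference is the mean log2(FPKM + 1) of the neurons labelled Pten-deficient minus that of the neurons labelled wildtype. It understates the change of genes near 0. Before the data were examined, 34 gene lists (pathways, complexes, channels and markers of other cell types) were fixed. The lists' members in the table were summarised by the median of their differences. For the 25 lists with at least 5 members in the table, the median was placed among 10000 random lists of the same size, drawn from 20 bins of the mean over the 8 libraries. A list was said to stand apart when its median lay in the outer 5% of the random medians, both tails together. The percentile describes these 8 libraries only, treats genes as independent, and is not a test of genotype. With 25 lists, 1.25 would stand apart by chance. On simulated data made from these 5814 genes with 20 genes per list, 7.5% of lists with no planted shift stood apart. With planted shifts of 1 and 2 on the log2 scale, 54% and 99% did. These rates hold for independent genes in lists of 20. They do not carry over to shorter lists or to genes that vary together.

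The rule for named genes was also fixed before the data were examined. It takes Pten, 6 serotonin neuron genes (Tph2, Slc6a4, Fev, Slc18a2, Ddc and Htr1a), and, among the 3389 genes with a mean of at least 2 whose Pten-deficient neurons lay all above or all below all wildtype neurons, the 12 largest differences in each direction. It also takes the 2 highest and 2 lowest members of each list. With no difference at all and no tied values, 2 of the 70 ways to split 8 neurons into 4 and 4 separate a gene in this way. Up to about 96.8 of the 3389 genes would then do so by chance, and tied zeros lower that number. Maob was named after its values were seen.

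Alternatives were pseudocounts of 0.1 and 5, a stricter filter (a mean of at least 3), rescaling each library to the same sum or by its median ratio to the geometric mean, group medians, leaving out listed zeros, means over list members, unmatched random lists, and leaving out each neuron. The planned run without the filter could not be made, since the deposited table is filtered at the same mean. Gene positions are from the GENCODE M1 annotation of NCBIM37, the assembly that mm9 names. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.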

Results

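Gene expression was profiled in single serotonin neurons of the dorsal raphe, the midbrain nucleus that supplies most serotonin to the forebrain, to compare neurons labelled wildtype with neurons labelled Pten-deficient. Pten encodes the lipid phosphatase that opposes PI3-kinase and so restrains Akt and mTOR signalling. The data comprised 4 libraries labelled wildtype and 4 labelled Pten-deficient, with 5814 genes listed. The number of genes listed above 0 ranged from 3259 to 4766 in the libraries labelled wildtype and from 2560 to 5294 in those labelled Pten-deficient. Only 1198 genes, 20.6% of the table, were above 0 in all 8 libraries. The libraries correlated weakly across genes, with a mean Pearson r of 0.36 over the 6 wildtype pairs, 0.37 over the 6 Pten-deficient pairs and 0.34 over the 16 pairs between genotypes; genes are not independent replicates.

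The summed FPKM of the listed genes was higher in every library labelled Pten-deficient (396858 to 478181) than in any labelled wildtype (230626 to 322689). The median difference over all genes was 0.54 on the log2(FPKM + 1) scale, and 62.4% of genes had the higher mean in the neurons labelled Pten-deficient. This median became 0.16 when each library was rescaled to the same sum and 0.022 when libraries were scaled by their median ratios. Differences below are on the deposited scale and should be read against this shift of 0.54. It was 0.30 without Pten-deficient library 2 and 0.91 without Pten-deficient library 1. For the 1198 genes above 0 in all 8 libraries the median difference was larger, at 0.77. Differences of abundant genes should be read against that value. The numbers of genes above 0 overlapped between the groups, and the library with the fewest, 2560, was Pten-deficient library 1.

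**Figure D1:**
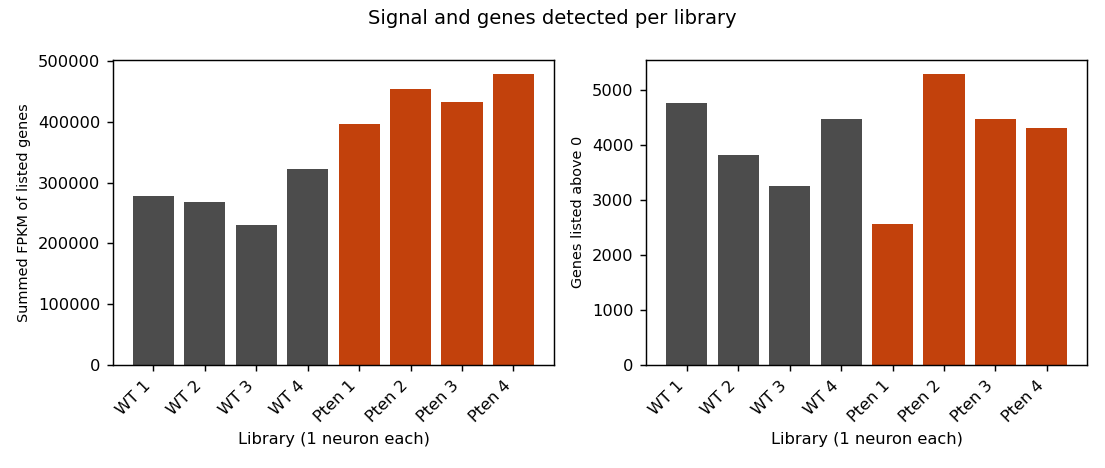
Left, the summed FPKM of the listed genes; right, the number of genes listed above 0; 1 bar per library, with wildtype (WT) in grey and Pten-deficient (Pten) in orange. The sums of the 4 Pten-deficient libraries, from 396858 FPKM, all lie above those of the wildtype libraries, up to 322689 FPKM, while the gene numbers overlap.

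Pten itself (chromosome 19, 32831987 to 32900650, plus strand, mm9) was not lower in the neurons labelled Pten-deficient. Its level was 4.47 ± 1.86 there and 3.65 ± 1.33 in those labelled wildtype (log2(FPKM + 1), mean ± SD, n = 4 neurons each), and the ranges overlapped. In FPKM, Pten was 152 in Pten-deficient library 1, and 9.44, 11.3 and 11.4 in libraries 2 to 4, against 10.5, 7.03, 45.8 and 4.69 in wildtype libraries 1 to 4. The difference of 0.83 became 0.19 when libraries were rescaled to the same sum and 0.10 by the median ratio, and without Pten-deficient library 1 it turned to -0.10. The labels do not say which part of the gene was removed, and an FPKM over the whole gene counts fragments from any exons that remain, so this value checks the genotype labels only weakly. The group names are therefore used only as labels, and every direction given here rests on them.

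Tph2, Slc6a4, Slc18a2 and Ddc were abundant in all 8 neurons. Tph2, the rate-limiting enzyme of neuronal serotonin synthesis (chromosome 10, 114515697 to 114622078), reached 10.50 ± 0.38 in the neurons labelled Pten-deficient and 10.07 ± 0.27 in those labelled wildtype (n = 4 each). Slc6a4, the serotonin transporter that takes serotonin back into the cell (chromosome 11, 76812105 to 76845842), was higher in every neuron labelled Pten-deficient than in any labelled wildtype, at 10.89 ± 0.82 against 8.85 ± 0.96, a difference of 2.05. In FPKM, Slc6a4 was 3453, 2746, 1259 and 1093 in Pten-deficient libraries 1 to 4, and 430, 539, 196 and 979 in wildtype libraries 1 to 4. The 2 groups overlapped once libraries were rescaled, where the difference was 1.36 by the sum and 1.24 by the median ratio. Slc18a2, the vesicular monoamine transporter (chromosome 19, 59335368 to 59370502), was at 8.86 ± 0.25 against 7.80 ± 0.72, with overlapping ranges, and its difference of 1.06 became 0.37 by the sum and 0.26 by the median ratio. Ddc, which converts the precursor to serotonin, was at 9.37 ± 0.67 against 9.22 ± 0.64, and Fev, the transcription factor also called Pet1, at 5.39 ± 1.29 against 5.41 ± 1.31. Under both scalings Tph2 and Ddc turned below 0, at -0.26 and -0.54 by the sum and -0.37 and -0.65 by the median ratio, and Fev came to -0.70 and -0.79. Ddc turned to -0.13 without Pten-deficient library 1 and to -0.097 without wildtype library 2, and Fev ran from -0.59 to 0.55 when 1 neuron was left out. The serotonin receptor list had only Htr1a and Htr5b in the table, with a median difference of 2.44. Htr1a, the serotonin autoreceptor, was listed at 2.43, 0, 5.64 and 4.12 in wildtype libraries 1 to 4 and at 1.57, 4.80, 4.45 and 0.11 in Pten-deficient libraries 1 to 4.

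Of the 26 genes fixed as serotonin neuron identity, 19 were in the table, and 12 had the higher mean in the neurons labelled Pten-deficient. Their median difference of 0.43 lay at percentile 27.2 of random lists of like expression, and it became -0.26 and -0.15 under the scalings by sum and by median ratio. It fell to 0.075 without Pten-deficient library 1, outside the range of random lists (percentile 0.855), and to 0.078 without wildtype library 1 (percentile 7.83). Within the list, Htr5b, a serotonin receptor, was listed at 0 in all 4 wildtype libraries and in Pten-deficient library 1, but at 7.42, 5.80 and 7.57 in Pten-deficient libraries 2 to 4. Pts, an enzyme that makes the cofactor of Tph2, was at 7.75, 7.70, 0 and 8.12 in the Pten-deficient libraries, and above 0 in wildtype library 3 alone, at 6.92. Maob, a monoamine oxidase, was at 9.66, 9.15, 9.30 and 8.45 in the Pten-deficient libraries and at 7.18, 6.34, 0 and 6.45 in the wildtype libraries, and the groups stayed apart under both scalings. It lay outside the rule for named genes and was chosen after its values were seen. Slc22a3, a low-affinity monoamine transporter, and Lmx1b, a transcription factor of serotonin neurons, were the lowest members, with differences of -1.78 and -2.04. Lmx1b rested on wildtype library 1, where it was at 8.33.

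**Figure D2:**
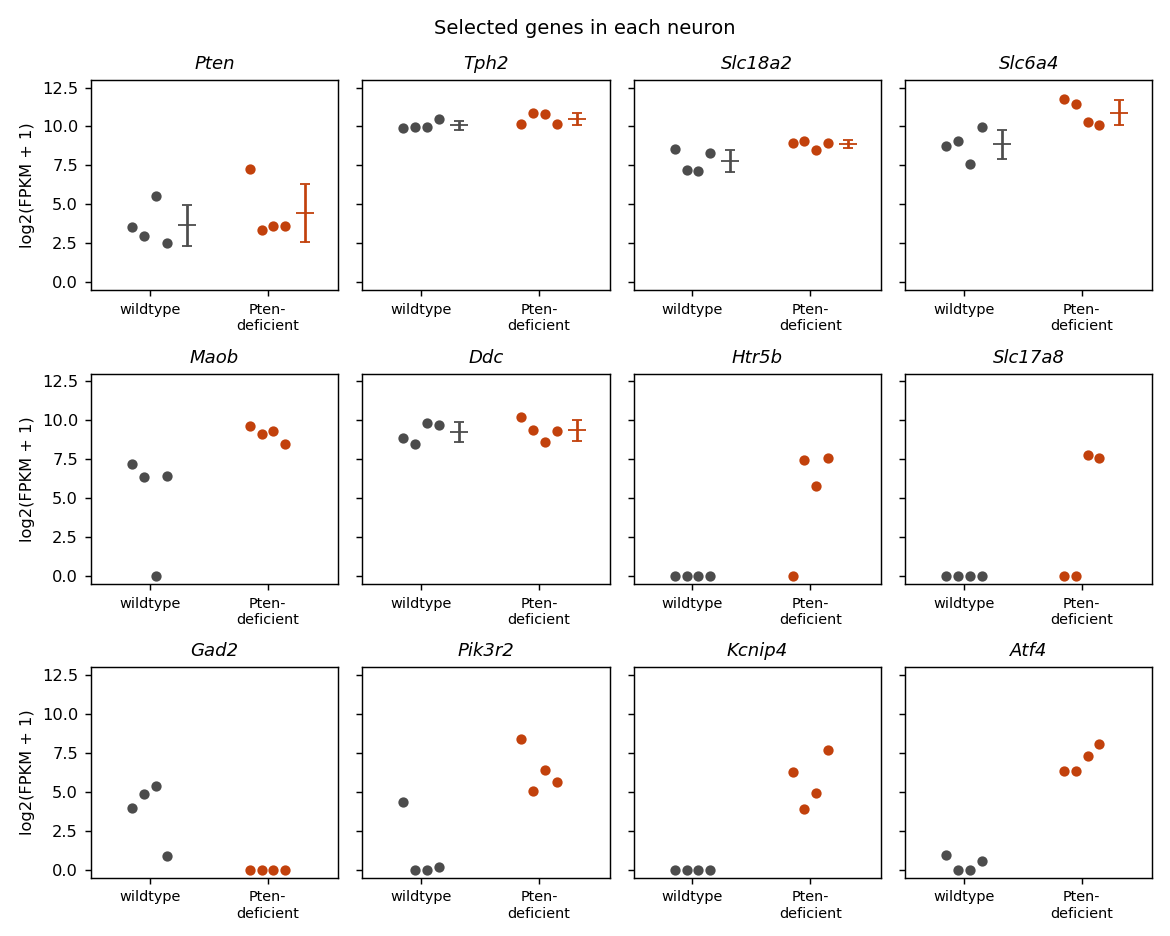
Level of 12 genes in log2(FPKM + 1); each point is 1 neuron, wildtype in grey and Pten-deficient in orange, and the bar is the mean with the SD over 4 neurons, drawn only for genes above 0 in all 8 libraries. Slc6a4, at 8.85 and 10.89 on average, separates the groups, while Pten and Tph2 overlap.

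Among the genes that separated the groups, the 12 largest positive differences belonged to Mal2, Atf4, Tmem179, Eef1e1, Polr2m, Polr2b, Nceh1, Bub3, Mgll, Paqr7, Tcp1 and the first of the 2 rows named Gm5506, in that order. Mal2, a membrane protein of apical and vesicle trafficking, was at 10.87, 8.70, 8.07 and 9.03 in the neurons labelled Pten-deficient and at 1.58, 0, 0.67 and 7.51 in those labelled wildtype. Atf4 (chromosome 15, 80085614 to 80087970), the transcription factor of the integrated stress response, was at 6.36, 6.35, 7.31 and 8.07 against 0.98, 0, 0 and 0.55. The RNA polymerase II genes Polr2m and Polr2b differed by 6.38 and 6.13. Bub3, known from the spindle checkpoint, was at 6.66, 6.15, 7.23 and 6.90 against 1.17, 0.68, 0.06 and 0.80. Mgll, the lipase that breaks down an endocannabinoid, was at 3.14 to 7.64 against 0 to 0.11, and Nceh1, a cholesterol ester hydrolase, at 5.16 to 8.51 against 0 to 0.90. Eef1e1, a component of the multi-tRNA synthetase complex, was listed at 0 in all 4 wildtype libraries and at 8.75, 2.10, 8.51 and 6.69 in the Pten-deficient libraries. Tcp1, a subunit of the chaperonin that folds actin and tubulin, differed by 5.96. The 2 rows of Gm5506 went opposite ways, so its value is uncertain.

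The 12 largest negative differences belonged to Fgf14, Gm15881, Ypel3, Zgpat, Nsmce2, B4galt3, Rgs11, Pisd-ps1, Ndrg2, Dync1li1, Olfr856-ps1 and 1500011B03Rik. Fgf14 (chromosome 14, 124377129 to 125076349), an intracellular member of its growth factor family that binds sodium channels, was at 4.40, 6.79, 8.04 and 7.16 in the neurons labelled wildtype and at 0, 4.10, 0.21 and 0 in those labelled Pten-deficient. Ypel3 differed by -5.15, Zgpat, a zinc finger repressor, by -5.07, and Rgs11, a regulator of G-protein signalling, by -4.47. Nsmce2, a SUMO ligase of a chromosome maintenance complex, was listed at 0 in all 4 Pten-deficient libraries and at 4.75, 0.89, 8.27 and 5.52 in the wildtype libraries. Dync1li1, a dynein light intermediate chain, was at 2.52 to 5.85 against 0 to 0.25. Gm15881 (annotated as a pseudogene), Pisd-ps1 and Olfr856-ps1 may share fragments with related genes and are uncertain. All 24 genes kept their direction under both scalings, which shows little, since their differences were far larger than the shift between the groups. Of them, 23 stayed separated after rescaling to the same sum (not Paqr7) and 22 after scaling by the median ratio (not Mal2 or Paqr7). Up to about 96.8 of the 3389 genes considered would separate by chance, fewer where zeros tie, so separation alone singles out none of them. The number that did separate is not given here.

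**Figure D3:**
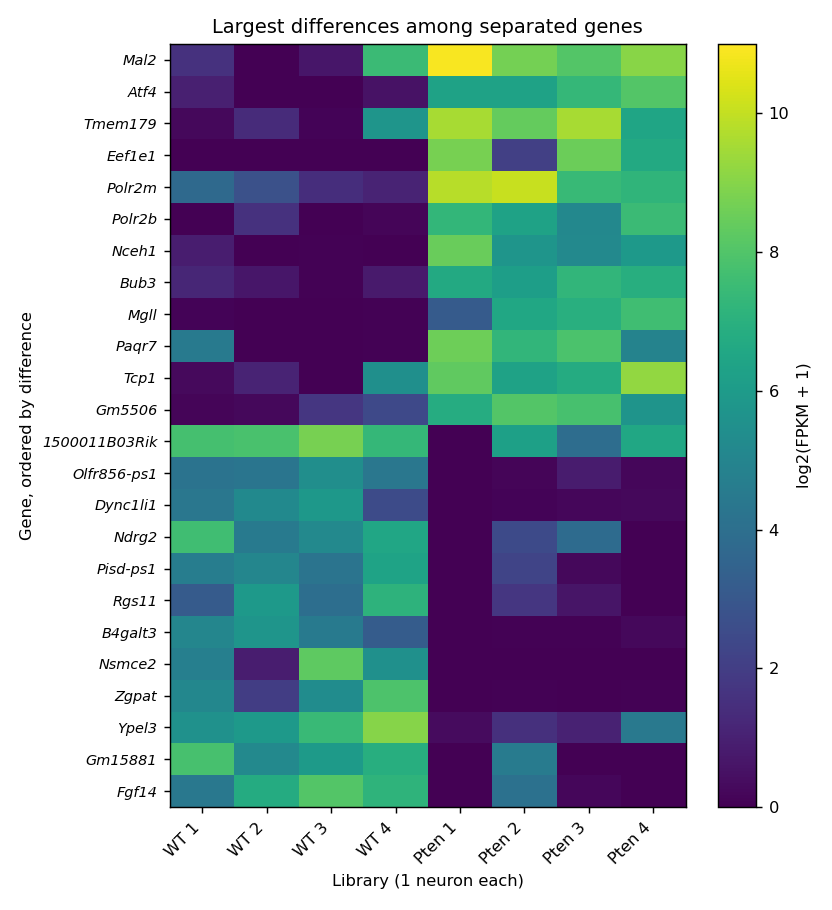
Level of the 24 ranked genes, as colour on a scale of log2(FPKM + 1), in each wildtype (WT) and Pten-deficient (Pten) library, ordered by the difference of group means. Values in Atf4 reach 6.35 to 8.07 in the Pten-deficient libraries against at most 0.98 in the wildtype libraries.

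The PI3K-Akt-mTOR pathway, which Pten restrains, did not stand apart as a list. Of its 39 genes, 23 were in the table; 13 had the higher and 10 the lower mean in the neurons labelled Pten-deficient. The median difference of 0.57 lay at percentile 50.7 of matched random lists, and became -0.13 and -0.22 under the scalings by sum and by median ratio. Leaving out any 1 neuron lowered it, to between -0.042 (without Pten-deficient library 2) and 0.41, at percentiles of 7.49 to 32.8. Pik3r2, a regulatory subunit of PI3-kinase (chromosome 8, 73292075 to 73300612), was at 8.38, 5.06, 6.42 and 5.64 in the Pten-deficient libraries against 4.33, 0, 0 and 0.22 in the wildtype libraries; the groups overlapped after scaling by the median ratio. Sgk1, a kinase activated downstream of PI3-kinase, was at 3.09 to 6.64 against 0 to 5.48. Eif4b, a translation initiation factor, and Tsc2, the mTOR inhibitor tuberin, had differences of -2.55 and -2.05. Because the list holds inhibitors such as Tsc2 beside activators, its median has no set direction. RNA levels also do not show whether the pathway was active. FoxO factors and their target genes had a median difference of 0.50 over 10 members (percentile 47.6), and this median ran from 0.087 to 0.96 when 1 neuron was left out. In that list Sod2, the mitochondrial superoxide dismutase, was at 5.49 to 6.49 against 0 to 4.29, and Bnip3, a mitophagy receptor, differed by 3.45, while Pink1, a mitophagy kinase, differed by -1.74 and Irs2, an insulin receptor substrate, by -1.14.

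Lists of growth and protein synthesis also lay within the range of random lists. For cytosolic ribosomal proteins the median was 0.63 over 78 members (percentile 20.8). In that list Fau and Rpl9 had differences of -3.61 and -3.40 and Rpl7a one of 4.44; both negative values include a listed 0 in Pten-deficient library 1. Translation factors had a median of 0.47 over 42 members (percentile 28.8), with Eif5a at 3.91 and Eef1d at -2.63. Amino acid response genes had a median of 0.83 over 16 members (percentile 75.9). Besides Atf4, Slc3a2, a subunit of amino acid transporters, was the highest of these at 3.19, and Ddit3, a stress transcription factor, the lowest at -1.29. The neurotrophin and growth factor list had a median of 0.48 over 11 members (percentile 45.3). When 1 neuron was left out, these medians ran from 0.23 to 1.11 for ribosomal proteins, 0.046 to 1.06 for translation factors, 0.44 to 1.41 for the amino acid response and 0.14 to 1.36 for neurotrophins. Ret, the receptor of GDNF family ligands, was at 5.82, 6.22, 3.84 and 4.33 in the Pten-deficient libraries against 0.21, 0, 0 and 0.02 in the wildtype libraries. The lowest member of the neurotrophin and growth factor list was Fgf14, with a difference of -5.52.

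GABA-A receptor and potassium channel genes stood apart from random lists. Of 14 GABA-A receptor genes, the subunits of the main inhibitory receptor, 5 were in the table, with a median difference of 2.67 at percentile 99.4. Gabrb1 and Gabrg2 had differences of 3.15 and 2.95, while Gabra1 had one of -2.02 and Gabrb2 one of -0.09, and the mean over the 5 genes, 1.33, lay at percentile 85.3. Of 42 potassium channel genes, 18 were in the table, 14 with the higher mean in the neurons labelled Pten-deficient, and the median of 1.51 lay at percentile 97.7. When 1 neuron was left out, the median ran from 1.20 to 2.33 for potassium channels and from 1.87 to 3.57 for GABA-A receptors. Kcnip4, an auxiliary subunit of A-type channels (chromosome 5, 48780743 to 49915940), was listed at 0 in all 4 wildtype libraries and at 6.28, 3.90, 4.96 and 7.73 in the Pten-deficient libraries. Kcnc1, a fast delayed rectifier, was at 5.62, 6.61, 6.96 and 5.36 against 5.36, 1.14, 0.48 and 0.08, and Kcnk9, a background potassium channel, differed by -1.57. The mean level of the potassium channel list was 3.89, 3.80 and 3.42 in Pten-deficient libraries 2 to 4, above the wildtype libraries (1.13 to 1.79), but 1.02 in Pten-deficient library 1. The mean level of the GABA-A receptor list overlapped between the groups, at 1.54, 3.90, 0.89 and 1.37 in wildtype libraries 1 to 4 and at 0.96, 3.81, 4.08 and 4.19 in Pten-deficient libraries 1 to 4. With 25 lists, 1.25 would stand apart by chance. Neither list did so with listed zeros left out (percentile 94.0 for GABA-A receptors and 96.1 for potassium channels), with a pseudocount of 5, or without wildtype library 1 or Pten-deficient library 2, 3 or 4. Potassium channels also did not after scaling by the median ratio (96.5) or without wildtype library 2 or 4, nor GABA-A receptors without wildtype library 3.

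**Figure D4:**
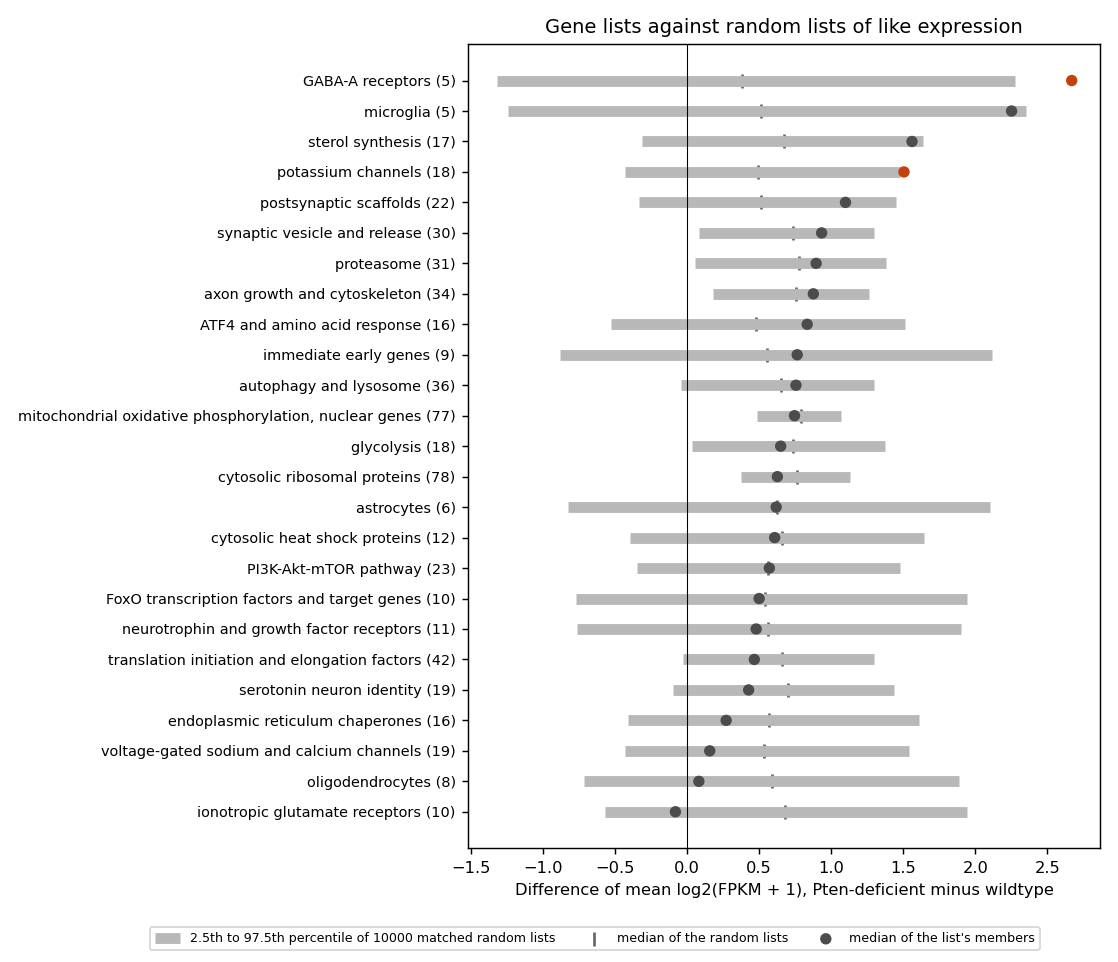
Median difference of each gene list (points, with the number of members in brackets) on the log2(FPKM + 1) scale, Pten-deficient minus wildtype; grey bars span the central 95% of 10000 random lists of like expression and ticks mark their median. Orange points, GABA-A receptors at 2.67 and potassium channels at 1.51, lie outside their bars.

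The other channel and synapse lists did not stand apart. Ionotropic glutamate receptors had a median of -0.08 over 10 members (percentile 11.2), which turned to 0.55 without Pten-deficient library 1 and 0.34 without wildtype library 4 and fell to -0.57 without wildtype library 1. Grik5 was lowest at -2.03 and Grin2b highest at 1.84. Sodium and calcium channels had a median of 0.16 over 19 members (percentile 22.5), with Scn1a, a sodium channel, at 3.62 and Scn9a at -1.43. That median turned to -0.16 without Pten-deficient library 2 and rose to 0.57 without library 4. Postsynaptic scaffolds had a median of 1.1 over 22 members (percentile 89.6). Gphn, the scaffold of inhibitory synapses, was at 4.52, 5.15, 3.05 and 5.94 in the Pten-deficient libraries against 0, 0, 0 and 1.88, while Shank2 and Shank1, scaffolds of excitatory synapses, had differences of -2.10 and -1.23. The synaptic vesicle list had a median of 0.93 over 30 members (percentile 75.8), from a lowest member at -2.31 to Snca, alpha-synuclein, at 3.87. Axon growth and cytoskeleton genes had a median of 0.88 over 34 members (percentile 68.9). Nefl, the light neurofilament, was at 5.82, 6.09, 6.80 and 9.65 in the Pten-deficient libraries against 1.87, 0.16, 3.08 and 0.06. Pfn2, an actin-binding profilin, differed by 4.80, and the lowest member of the axon growth list by -1.27. Immediate early genes had a median of 0.76 over 9 members (percentile 61.4), but one of 0.023 without wildtype library 4 and 1.70 without Pten-deficient library 3. Leaving out 1 neuron gave medians of 0.77 to 1.43 for postsynaptic scaffolds, 0.45 to 1.13 for synaptic vesicles and 0.69 to 1.29 for axon growth.

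Sterol synthesis genes lay just inside the range of random lists, with 14 of 17 members higher in the neurons labelled Pten-deficient and a median of 1.56 (percentile 96.4). Sc5d and Fdft1, enzymes of cholesterol synthesis, had differences of 4.71 and 3.76, and Mvd and Srebf2 differences of -1.38 and -0.76. Leaving out 1 neuron moved the median of the list between 0.97 and 2.20 and its percentile between 83.7 and 99.7. With listed zeros left out the percentile was 73.0. Oxidative phosphorylation genes of the nucleus had a median of 0.75 over 77 members (percentile 41.8) and glycolysis genes 0.65 over 18 (percentile 39.6). Proteasome genes (0.90, percentile 62.7), autophagy and lysosome genes (0.76, percentile 62.3), endoplasmic reticulum chaperones (0.27, percentile 27.5) and cytosolic heat shock proteins (0.61, percentile 45.5) were also within range. Without wildtype library 3 the proteasome and chaperone medians turned to -0.093 and -0.017, and they reached 1.39 without wildtype library 4 and 1.02 without Pten-deficient library 1. The medians for leaving out 1 neuron ran from 0.34 to 1.08 for autophagy, 0.20 to 0.87 for heat shock proteins, 0.51 to 1.12 for oxidative phosphorylation and 0.27 to 1.13 for glycolysis. Hspa8, the constitutive heat shock chaperone, had a difference of 1.33 and separated the groups, which overlapped after scaling by the median ratio. The lowest member was at -1.68 among heat shock proteins and at -4.24 among endoplasmic reticulum chaperones. With all 8 neurons, 1 of the 25 list medians was below 0 on the deposited scale, 10 after rescaling to the same sum and 14 after scaling by the median ratio. These counts largely follow the shift over all genes, which the scalings reduced, and single out no list.

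Transcripts of other cell types were present in both groups. Oligodendrocyte markers had a median difference of 0.08 over 8 members but a mean of -0.086, and the median ran from -1.13 without wildtype library 3 to 1.05 without wildtype library 1. Their mean level ran from 1.07 to 7.54 in the wildtype libraries and from 2.73 to 4.99 in the Pten-deficient libraries. Astrocyte markers had a median of 0.62 over 6 members (percentile 49.7), which turned to -0.16 without wildtype library 3 and rose to 1.47 without Pten-deficient library 1. Microglia markers had one of 2.25 over 5 (percentile 96.0), which fell to 0.87 without Pten-deficient library 3. The 3 markers of GABAergic neurons in the table had a median difference of -3.30. Gad2, a GABA-synthesising enzyme, was at 3.97, 4.87, 5.38 and 0.91 in the wildtype libraries and at 0, 0, 0 and 0.02 in the Pten-deficient libraries, and Slc6a1, the GABA transporter, at 5.18, 4.12, 4.61 and 4.81 against 0.50, 0, 5.02 and 0. Hba-a2, an alpha-globin of red blood cells listed on 2 rows, was at 7.23, 6.41, 4.61 and 0.15 in the wildtype libraries on its first row and at 0, 0, 1.67 and 0 in the Pten-deficient libraries. Its second row reached 10.69 in Pten-deficient library 4. The 2 rows together had a median difference of -2.85. The list fixed as oligodendrocyte precursors had only Bcas1 in the table, with a difference of -0.32. This 1 gene does not tell precursors from other oligodendrocyte cells. The 1 glutamatergic marker, Slc17a8, differed by 3.84. No member of the endothelial, ependymal, or dopaminergic and noradrenergic lists, or of the mitochondrially encoded proteins, was in the table.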

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

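All tests of explanations in this part were chosen after the result was seen. In 120 groups of 4 neurons examined, 13 had a neuron whose distance to the nearest other took up most of the group's range, where chance gives about 6. For Pten the ratio of that gap to the range was 0.94, since Pten-deficient library 1 was at 7.25 and the others at 3.38 to 3.63. For Tph2 it was 0.87, with wildtype library 4 at 10.47 and the others at 9.89 to 9.96. Pten-deficient library 1 also stood apart for the mean levels of the PI3K-Akt-mTOR list (0.84), the GABA-A receptor list (0.88) and the potassium channel list (0.84), each time at the low end. Pten-deficient library 2 stood apart at the high end for Fgf14 (0.95), Gm15881 (1) and Pisd-ps1 (0.90). In the wildtype neurons the gap took up 0.86 of the range for Olfr856-ps1 (library 3), 0.92 for Polr2b (library 2), 0.95 for Nceh1 and 0.99 for Paqr7 (both library 1). The share of the summed FPKM on Rn45s, the ribosomal RNA precursor, was 1.03% in Pten-deficient library 4 against 1.36% to 1.41% in the others, a ratio of 0.86.

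The potassium channel list was higher in Pten-deficient libraries 2 to 4 than in any wildtype library and low in library 1, which has the fewest genes above 0. The mean level of Gad1, Gad2 and Slc6a1 goes against more RNA of GABAergic neurons in those libraries than in the wildtype ones. It was 0.99, 1.67 and 0.67 in Pten-deficient libraries 2 to 4 against 1.91 to 4.78 in the wildtype libraries. Single genes did not all go this way. Slc6a1 in library 3 and Gad1 in libraries 2 and 4 lay within the wildtype range, so some such RNA is not excluded. The median group difference of the 3 genes, -3.30, also includes library 1. A larger number of detected genes stays open as a candidate explanation. The list's excess over genes of like expression lay 0.33, 0.82 and 0.52 above the highest wildtype value in Pten-deficient libraries 2 to 4 (pooled SD 0.59). Among random lists of like expression these libraries were at percentiles 89.4, 97.3 and 90.9, and wildtype library 1 was low, at 0.61. The list was singled out for being high in these same libraries, so its excess there cannot decide the question. The list level of library 4 lay at least 1.67 above those of the wildtype libraries with at least as many genes (pooled SD 0.98). For the same reason this level cannot decide the question either. It is also on the deposited scale, where the summed FPKM of library 4 was higher than that of any wildtype library. The genotype and the type of serotonin neuron drawn also stay open, untested.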

How the results depend on the processing

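No paired analysis was possible because no test was made across single neurons and the numbers in the titles name no animal. Of the 417 values of the 30 single-gene results other than Pten, 44 moved by more than the SD between neurons, all under the pseudocounts or the scalings. Where the groups had been separate, no sign changed. That was fixed in advance for every alternative but the scalings, because separate groups keep their order there, so it does not show stability. Pten ranged from -0.10 to 1.46 over the runs that leave out 1 neuron. List medians that moved by more than that SD were as follows. With a pseudocount of 0.1, GABA-A receptors came to 4.41, microglia to 3.85 and sodium and calcium channels to 0.45. With the stricter filter, sodium and calcium channels came to 0.59. With libraries rescaled to the same sum, the PI3K-Akt-mTOR list came to -0.13, serotonin identity to -0.26 and sodium and calcium channels to -0.13. With the median ratio they came to -0.22, -0.15 and -0.28, axon growth to 0.27, synaptic vesicles to 0.13 and postsynaptic scaffolds to 0.51. With zeros left out, FoxO came to 1.66, immediate early genes to 1.91 and sodium and calcium channels to 0.44. With means over members, serotonin identity came to 0.89 and sodium and calcium channels to 0.57. Leaving out 1 neuron gave -0.16 to 0.57 for sodium and calcium channels, -0.042 to 0.41 for the PI3K-Akt-mTOR list, 0.87 to 2.43 for microglia and 0.14 to 1.36 for neurotrophins. The cause of these moves was not tested. The percentile of the potassium channel list ran from 90.5 to 99.8 and that of GABA-A receptors from 93.7 to 99.7 when 1 neuron was left out. Neither list stood apart with a pseudocount of 5, with zeros left out, or with wildtype library 1 or Pten-deficient library 2, 3 or 4 left out. Nor did potassium channels without wildtype library 2 or 4, or GABA-A receptors without wildtype library 3. Under the stricter filter neither list was run, for too few members, and none of the 16 lists left stood apart. Other lists stood apart under single alternatives. These were sterol synthesis with means over members (percentile 97.6) or without wildtype library 2 (99.7) or Pten-deficient library 1 (98.6) or 2 (98.5), serotonin identity without Pten-deficient library 1 (0.855), microglia after rescaling to the same sum (97.7), and oligodendrocytes without wildtype library 3 (1.42) or 4 (1.31). Over the runs that leave out 1 neuron these percentiles ran from 83.7 to 99.7 for sterol synthesis, 0.855 to 49.6 for serotonin identity, 67.0 to 96.1 for microglia and 1.31 to 66.7 for oligodendrocytes. Sterol synthesis was at 73.0 with zeros left out and at 41.9, with a median of 0.73, with only members above 0 in every library. A run without the filter on the mean was not made, since the deposited table holds only genes with a mean of at least 1. Restricting lists to members above 0 in every library, an alternative added after seeing the data, left 14 lists, none of which stood apart, but neither potassium channels nor GABA-A receptors were among them. The unknown depth and the 8.94% to 56.0% of genes listed at 0 per library limit every value of a low gene.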

Other observations

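All tests of explanations in this part were chosen after the results were seen. The neurons differed in transcripts that can mark subtypes of serotonin neuron, though Gad1 is also among the markers of GABAergic neurons used above. Whether these values reflect the type of neuron drawn or RNA of other cells was not tested. Slc17a8 (chromosome 10, 89036765 to 89083998), the vesicular glutamate transporter VGLUT3, was at 7.77 and 7.58 in Pten-deficient libraries 3 and 4 and listed at 0 in the other 6 libraries. Gad1, a GABA-synthesising enzyme, was at 5.19, 4.59, 4.17 and 0 in the wildtype libraries and at 0, 2.96, 0 and 1.98 in the Pten-deficient libraries. The libraries with Htr5b above 0 were Pten-deficient libraries 2 to 4.

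Most genes were higher in the libraries labelled Pten-deficient. Among the listed genes, a few abundant ones taking the signal in the wildtype libraries are argued against. The 10 highest listed genes held only 1.50 percentage points more of the summed FPKM there. A shift of signal to longer listed genes is argued against too. The ratio of FPKM-weighted gene lengths was 1.02, wildtype over Pten-deficient, from the 5535 genes with a GENCODE M1 length. Neither value covers abundant genes missing from the table, such as the mitochondrially encoded ones. Fragments outside the listed genes, or another total in the scaling, cannot be told apart from a change with genotype. FPKM times length, summed over the listed genes, was 1.58 times as high in the Pten-deficient libraries, but with alike lengths this restates the higher summed FPKM and decides nothing. As a share of fragments it came to 65.8% to 90.7% in the wildtype libraries and to an impossible 114% to 131% in the Pten-deficient libraries, so the lengths or the total do not hold.

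Slc6a4 was higher in every neuron labelled Pten-deficient. The higher scale of those libraries cannot be told apart from a specific change, since after scaling by the median ratio the difference was 1.24, larger than the pooled SD of 0.94, but the groups overlapped. Most values go against a larger share of neurons of the Slc17a8 type as the source of the higher Slc6a4. Pten-deficient libraries 1 and 2, the 2 with Slc17a8 listed at 0, had the higher Slc6a4 (11.75 and 11.42), while libraries 3 and 4 were at 10.30 and 10.10 and, by the median ratio, at 9.46 and 9.31, below wildtype library 4 at 9.75. That explanation is left open, as is the genotype, only because a listed 0 can be a failed estimate. A failed estimate has less room in library 2 (8.94% of genes and 0 of 23 widely expressed genes at 0) than in library 1 (56.0% and 6).

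Genes were also grouped by the letters that open their symbols, a scan made after the lists had been examined. Of 59 groups with at least 10 genes, 3 lay in the outer 5% of matched random lists, where chance gives 2.95. The Ppp group, 41 genes that mostly encode subunits of protein phosphatases, had a median difference of -0.64 against 0.52 for random lists, at percentile 0.02, with 27 genes lower. Leaving out 1 neuron moved this median between -1.04 and -0.10, and its percentile stayed at or below 1.65. The Rnf group, 39 RING finger genes, had a median of 1.68 at percentile 99.9, with 30 genes higher. Its median ran from 1.02 to 2.27 when 1 neuron was left out. The Timm group of 12 genes of mitochondrial import had a median of -0.52 at percentile 1.75. The Rnf group lay inside the central 95% without Pten-deficient library 3 (percentile 96.95). The Timm group did so without wildtype library 3 (2.8) or 4 (4.25) or Pten-deficient library 1 (6.4), 2 (6.15) or 3 (3.15), and its median turned to 0.23 without Pten-deficient library 1. After rescaling to the same sum and by the median ratio, the medians were -1.15 and -1.21 for Ppp, 1.69 and 1.24 for Rnf, and -1.07 and -1.07 for Timm. Both scalings lower the Pten-deficient libraries against the wildtype ones. Negative medians were therefore unlikely to turn, and the kept directions of Ppp and Timm show little.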
